A study of Homo sapiens with 8 samples.

How the data were processed

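RNA was sequenced from 8 libraries labelled as HepG2, a human liver carcinoma line that secretes many hepatocyte proteins. Per the labels' protocols, cells were infected with lentivirus, total RNA was taken with Trizol, ribosomal RNA was depleted, fragments were copied from random hexamers, and UNG digestion of the second cDNA strand kept the strand information. The labels give 3 factors with 2 levels each: a hairpin against the long noncoding RNA glycoLINC, a hairpin against MYC, and medium with or without serine and glycine. Each of the 8 combinations has 1 library. Nothing in the labels says whether the libraries came from separate cultures on separate days. With 1 library per combination, p-values measure departures of these libraries from the fitted model and not a spread between replicates. Such departures may be technical.

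The deposited values are FPKM, normalised to transcript length and library size, in a table of 112430 RefSeq mRNA transcripts and a table of 215170 Ensembl transcripts, coding and noncoding together. Per the submitters' processing notes, CASAVA 1.8, fastp 0.20.0, Bowtie2 2.3.1, eXpress 1.5.1, edgeR and the genome build hg38 were used, with no role or order stated. The annotation release and any filter are not given in the sources used here. FPKM per transcript divides reads among overlapping isoforms, so sums per gene are steadier than single transcripts. Reads shared between close paralogs, such as the histone, ribosomal protein and BOLA2 families, may be divided unevenly, and values of such genes are uncertain. Among transcripts with low values in both libraries of a pair, at most 4.60% shared the most common ratio, so whole reads were not recovered from the values. The depth of each library is therefore unknown, and no counting interval is given. Summed FPKM of the mRNA table ran from 380598 to 451533, and no pair of columns held identical values.

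RefSeq accessions were matched to gene symbols through a reference gene table of assembly GRCh38.p14, used for names only and for no coordinates. Of the mRNA transcripts, 84482 (75.1%) matched, and their FPKM were summed by symbol into 19269 genes. The 27948 unmatched transcripts, 27494 of them predicted models, held 5.02% to 6.24% of the FPKM of a library and were left out. Ensembl transcripts were tested singly under their identifiers because the files do not pair them with names. For the same reason glycoLINC itself, other long noncoding RNAs and mitochondrially encoded transcripts were not analysed here by name.

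Genes with a mean FPKM of at least 1 over the 8 libraries (10363 genes) were tested with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1) with an intensity trend. A fold change on this scale understates the change of low genes. The planned model had additive effects of the 3 factors, each estimated from 4 matched pairs of libraries, with 4 residual degrees of freedom. Each pairwise interaction was tested by adding its term, with 3 residual degrees of freedom. Benjamini-Hochberg adjusted p below 0.05 was the threshold. The 87405 Ensembl transcripts with a mean FPKM of at least 0.5 were fitted apart on log2(FPKM + 0.1), as planned for noncoding RNA. In an additive fit any departure from additivity enters the residual and weakens the test. After the data were seen, contrasts of each knockdown alone, of both knockdowns, and of each knockdown on top of the other were added from the fit with the glycoLINC by MYC term. They average over the 2 media and have 3 residual degrees of freedom. Their residual holds any difference in the response to medium between hairpin labels, mixed with noise, and their p-values rest on it. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

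The tests, the alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members (22 lists) were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. Counts of members are given over all genes and adjusted over the list alone. Another 5 lists of cell type genes were written after the data were first seen. For single pairs of libraries no test was run; the median of a list was ranked among 10000 random lists of the same size matched on mean expression. The correlation of the responses to the 2 knockdowns across genes was set beside values simulated without effects, with each gene drawn independently.

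Named genes were MYC; up to 8 genes that rose and 8 that fell most among those past the threshold with a mean FPKM of at least 5 and the same direction in all 4 matched pairs; where fewer than 4 passed in a direction, the 4 with the smallest p; up to 4 members with the smallest p from each list described; and 15 genes of serine synthesis, one-carbon metabolism, amino acid stress and glycolysis whatever their change. From each interaction up to 3 genes in each direction were taken. Genes named outside this rule are said to be so, and the results of some single genes are not reported here. For the contrasts of each knockdown alone, added later, the same rule was applied, but directions were compared only in the matched pairs without the other hairpin. A gene named there can go the other way in a pair with the other hairpin.

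On simulated data built from these libraries for the MYC knockdown comparison (10363 genes, 200 of them changed), the additive fit recovered 68% of changes of 1 on the log2 scale, 92% of 2, 100% of 3 and 98% of 4, with 9 false calls. With an interaction term it recovered 34%, 78%, 100% and 100%, with 7 false calls. The simulated changes were the same in every library with the MYC hairpin, and noise was drawn independently for each gene. These rates therefore do not hold for genes whose response departs from additivity. Alternatives were another pseudocount, a shift of each library to a median ratio of 0, quantile normalisation, no filter or a stricter one, a robust fit without trend, and leaving out each library in turn.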

Results

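Expression was measured in 8 libraries labelled as HepG2 cells. The labels cross a hairpin against MYC, a transcription factor that drives growth genes, with a hairpin against glycoLINC, a long noncoding RNA that the study ties to the lower steps of glycolysis, and with removal of serine and glycine from the medium. Each of the 8 combinations was a single library, so a difference between a single pair of libraries has no replicate check. The p-values below rest on the matched pairs of a factor in 1 pooled fit. Read depth is unknown because only FPKM are used, and the summed FPKM of the mRNA table ran from 380598 to 451533. Libraries are named by their labels throughout, and "starved" stands for the label of medium without serine and glycine.

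The targeted gene MYC was at 523 FPKM in the library labelled control and at 5.77 FPKM in the library labelled MYC knockdown. It was at 8.76 FPKM in the library labelled double knockdown and also low, at 16.4 FPKM, in the library that carried only the glycoLINC label. In starved medium MYC was at 528 FPKM in the control library, 161 FPKM with the MYC hairpin, 169 FPKM with the glycoLINC hairpin and 55.2 FPKM with both. MYC was lower in the library with the MYC hairpin in 4 of 4 matched pairs, with log2 differences of −6.28, −0.83, −1.71 and −1.60. The additive log2 fold change was −2.60 ± 0.82 (SE, limma adjusted p = 0.120) and did not pass the test, with −3.12 to −1.61 when each library was left out. The level of glycoLINC, the other target, was not analysed here.

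The libraries did not express the genes that mark HepG2 cells. Of 29 genes of hepatocyte secretion and identity, all with a named transcript in the table, 1 had a mean FPKM of at least 1: CEBPA, a transcription factor also active in blood cells, at 1.47 FPKM. ALB, which encodes serum albumin, was at most 0.260 FPKM in any library, and AFP, the fetal liver protein that HepG2 cells secrete, was listed at 0 in all 8 libraries. The median over the list of the highest FPKM in any library was 0.113. Genes of B lymphocytes were abundant: MS4A1, which encodes CD20, ran from 234 to 880 FPKM, CD79A of the B cell receptor from 223 to 624 FPKM, and PAX5, the transcription factor of B cell identity, from 57.9 to 134 FPKM. Of a list of 14 B lymphocyte genes, 13 had a mean of at least 10 FPKM in these libraries. The exception, BANK1, had a mean of 0.00556 FPKM. Of 8 genes each, the lists of T lymphocyte and monocyte genes had 1 with a mean of at least 1 FPKM and the erythroid list had 0. The lists fixed for other cell types gave 2 of 10 fibroblast genes, 4 of 10 blood and endothelial genes and 2 of 10 epithelial genes at that level. The 4 were PTPRC (CD45), CD3E of T lymphocytes (mean 6.54 FPKM), and LYZ (14.9 FPKM) and CD68 (5.18 FPKM) of monocytes and macrophages. The label HepG2 thus goes against the gene content of all 8 libraries, and each direction given below is a direction between labels.

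**Figure D1:**
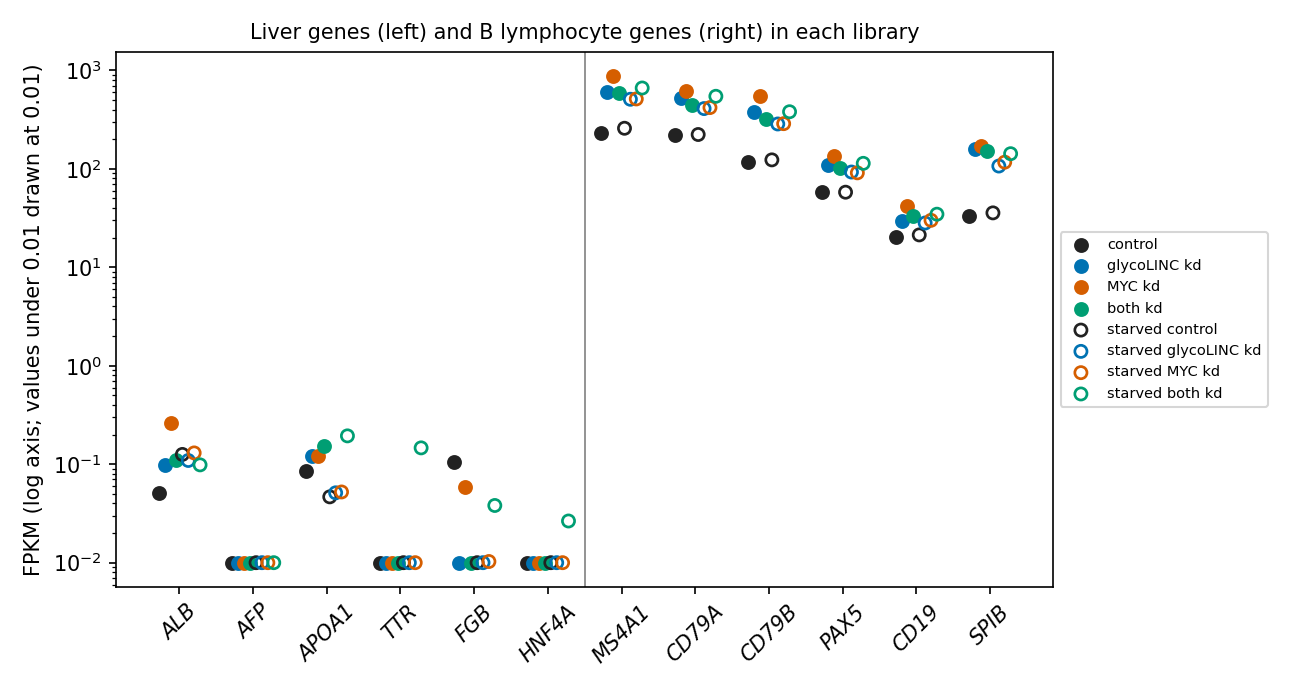
FPKM on a log axis of genes of hepatocytes and of B lymphocytes in each of the 8 libraries, each point 1 gene in 1 library. ALB stays at or below 0.260 FPKM, while MS4A1 lies between 234 and 880 FPKM.

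Differences between libraries did not follow the 3 labels evenly. Over 7985 genes with a mean FPKM of at least 5, the libraries labelled control and starved control differed at least 2-fold in 22 genes, and the libraries labelled glycoLINC knockdown and double knockdown in 23 genes. The closest pair carried different hairpin labels: starved glycoLINC knockdown and starved MYC knockdown differed in 15 genes. The control library differed from the MYC knockdown library in 2606 genes (857 higher and 1749 lower in the knockdown) and from the glycoLINC knockdown library in 1770 genes (714 higher and 1056 lower). In starved medium the same pairs differed in 891 and 809 genes. With a pseudocount of 0.1 the 22 genes became 46 and the 23 genes 47. No test was run on single pairs.

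**Figure D2:**
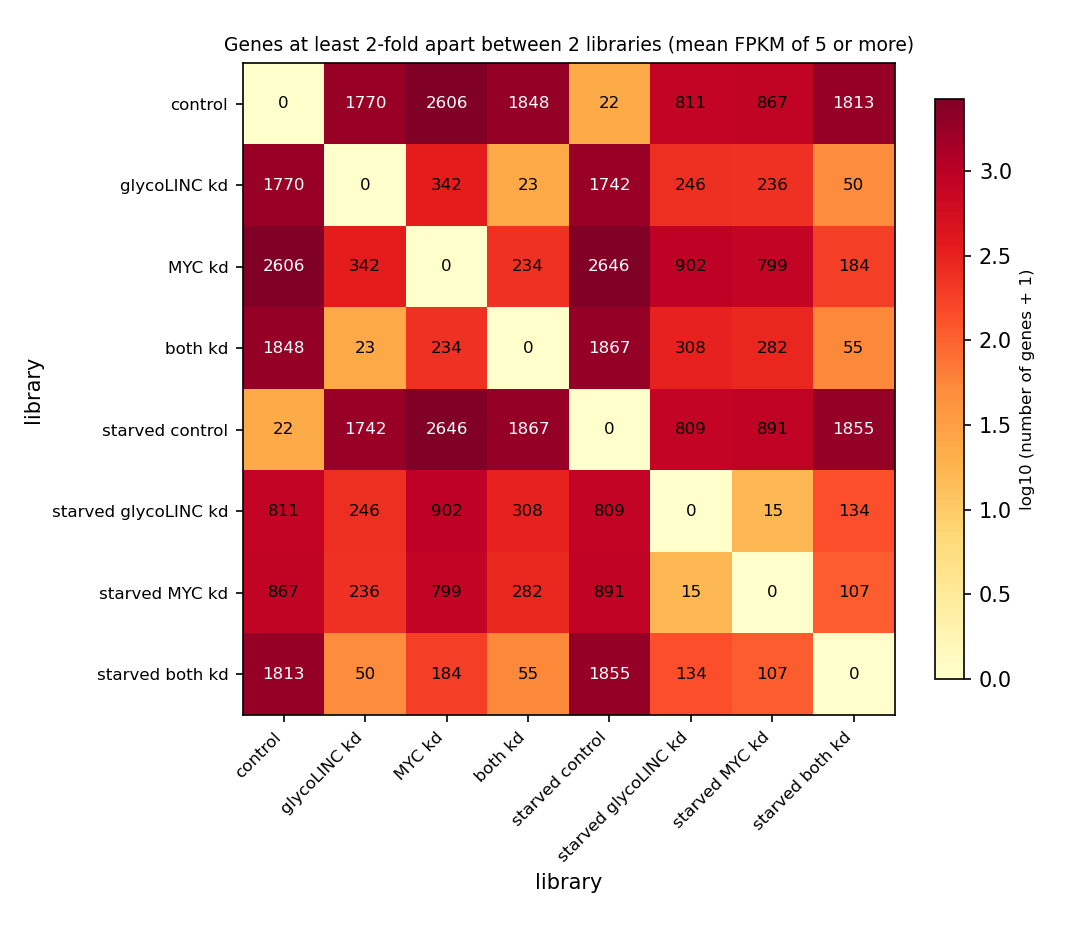
Number of genes at least 2-fold apart (log2 of FPKM + 1, 7985 genes with a mean FPKM of at least 5) for each pair of the 8 libraries, rows and columns named by label. The pair of control and starved control differs in 22 genes and the pair of control and MYC knockdown in 2606.

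The comparison of media asks how cells adapt to the loss of serine and glycine. Genes of the 3-step serine synthesis pathway had higher average values in the starved libraries, with log2 fold changes of 0.74 ± 0.46 (SE) for PHGDH, which opens the pathway, 1.29 ± 0.52 for PSAT1 and 0.62 ± 0.28 for PSPH. None of them passed the test (adjusted p = 0.931 for each). The amino acid stress genes ASNS (asparagine synthetase, 0.84 ± 0.33), ATF4 (0.40 ± 0.26), TRIB3 (0.36 ± 0.15), DDIT3 (0.15 ± 0.14) and CHAC1 (1.16 ± 0.41) did not pass either. In the pair without hairpins, PSAT1 went from 130 to 165 FPKM and ASNS from 43.4 to 57.9 FPKM. limma called 0 of 10363 genes, with 243 at an unadjusted p under 0.05 and a smallest adjusted p of 0.931. The closest to the threshold were PM20D2 (0.99 ± 0.17), NICOL1 (1.26 ± 0.23), TBC1D4 (19.9 to 25.9 FPKM in the pair without hairpins) and TMEM129 (0.42 ± 0.12) with higher values, and TMEM80 (−0.46 ± 0.12), MT1X (a metallothionein, −0.50 ± 0.13), AGAP9 (−0.46 ± 0.13) and ZNF765 (−0.39 ± 0.13) with lower ones.

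Other enzymes of one-carbon metabolism and glycolysis were also short of the threshold in starved medium (adjusted p = 0.931 for each). SHMT2 stood at 0.24 ± 0.21 and MTHFD2 at 0.45 ± 0.31, both mitochondrial folate enzymes. The glycolytic genes stood at 0.13 ± 0.18 (GAPDH), 0.34 ± 0.23 (PGK1), 0.27 ± 0.24 (PGAM1), 0.63 ± 0.37 (ENO1), 0.13 ± 0.15 (PKM) and 0.71 ± 0.43 (LDHA, lactate dehydrogenase). MYC itself averaged 2.60 ± 0.82 higher, from log2 differences of 0.01 in the pair without hairpins and of 3.29, 4.58 and 2.53 in the pairs with hairpins. With the preset correlation camera placed 11 lists higher and 1 lower of the 22 tested. The higher ones included nucleolar MYC targets (28 genes, mostly of ribosome production, median log2 0.83), purine and pyrimidine synthesis (16 genes, 0.58), tRNA synthetases (20 genes, 0.37), amino acid response (19 genes, 0.36), amino acid transporters (14 genes, 0.55) and serine, glycine and one-carbon genes (16 genes, 0.28). For each of these adjusted p = 0.626 with an estimated correlation. Fatty acid synthesis (10 genes, median 0.39), cholesterol synthesis (23 genes, 0.18), lower glycolysis (9 genes, 0.37) and heat shock genes (9 genes, 0.18) were placed higher with the same adjusted p = 0.626 with an estimated correlation. S phase genes (26 genes, median 0.25) were placed higher and interferon response genes (25 genes, −0.22) lower, with adjusted p = 0.683 with an estimated correlation. No list had a member past the threshold, 0 over all genes and 0 adjusted over the list alone. Signs differed for the G2/M list (24 genes, median 0.05, test lower) and the immediate early list (6 genes, median −0.07, mean 0.01).

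In the pair of libraries without hairpins, which has no replicate check, the amino acid response list had a median log2 difference of 0.16 (16 of 19 genes higher), the 99.9th percentile of random lists. The ribosomal proteins (0.12, 78 of 83 genes higher) lay at the 99.9th percentile, tRNA synthetases (0.11) at the 98.5th, amino acid transporters (0.13) at the 97.9th, p53 targets (0.11) at the 97.4th, hypoxia genes (0.12) at the 94.2nd, immediate early genes (0.14) at the 91.6th and serine, glycine and one-carbon genes (0.09) at the 90.0th. Random lists drew genes independently, so these percentiles are not chance levels for genes that move together. The nucleolar MYC targets (0.05) lay at the 57.8th percentile and interferon genes (0.07) at the 65.0th in this pair, against medians of 1.24 and −0.40 in the pair labelled glycoLINC knockdown. Without hairpins, purine and pyrimidine (0.05), fatty acid (0.06) and cholesterol synthesis (0.04) lay at the 63.3rd, 71.1st and 63.4th percentiles. Lower glycolysis (0.11), heat shock (0.05) and S phase genes (0.02) lay at the 83.5th, 37th and 19th. For these 6 lists the pair labelled glycoLINC knockdown had medians of 1.03, 0.55, 0.19, 0.43, 0.01 and 0.25. Genes of adherent epithelial cells also differed in the pair without hairpins: KRT7 went from 0.0256 to 1.54 FPKM, KRT17 from 0.0301 to 4.25 FPKM and S100A6 from 0.238 to 4.49 FPKM, and 8 of 16 such genes were at 1 FPKM or more in the starved library against 4. Among the 22 genes at least 2-fold apart, chosen here after their values were seen, were FAS, a death receptor (2.50 to 7.18 FPKM), DICER1, the microRNA-processing enzyme (4.80 to 12.6 FPKM), and CCL4, a chemokine (2.76 to 0.592 FPKM).

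The comparison of libraries with and without the MYC hairpin asks which transcripts depend on MYC. The libraries labelled MYC knockdown alone were set against the libraries without hairpins in the same medium. The residual behind these p-values holds differences in the response to medium between hairpin labels. Starved and unstarved MYC knockdown libraries differed at least 2-fold in 799 genes, against 22 for the control libraries. All 28 nucleolar MYC targets, mostly genes of ribosome production, fell and 24 of 25 interferon response genes rose, and for both lists adjusted p = 0.589 with an estimated correlation. MYC fell by 3.99 ± 0.90 (SE, log2, adjusted p = 0.0146), the proline synthesis gene PYCR1 by 3.21 ± 0.66 (adjusted p = 0.0111) and the HSP90 cochaperone gene FKBP4 by 3.46 ± 0.69 (adjusted p = 0.0105). The interferon-induced genes RSAD2 (4.12 ± 0.29, adjusted p = 0.00175), IFIT2 (3.57 ± 0.17, adjusted p = 0.000459) and CMPK2 (3.50 ± 0.18) rose. So did IFI6 (4.41 ± 0.50), ZBP1 (a sensor of viral nucleic acid, 3.92 ± 0.34), SLFN5 (3.87 ± 0.19), the chemokine gene CCL3 (3.78 ± 0.40) and CD82 (3.37 ± 0.46). HPDL (−3.59 ± 0.86), BOLA2B (−3.31 ± 0.65), GALNT18 (−3.22 ± 0.74), the mitochondrial ribosomal gene MRPL34 (−3.19 ± 0.84) and NPW (−3.05 ± 0.89) fell. In all, 4261 of 10363 genes passed limma's test, 1604 up and 2657 down, with a median over all genes of −0.14, to which these changes are relative. Quantile normalisation moved the division to 1948 up and 1986 down. B lymphocyte genes moved with these groups: 12 of 13 rose, among them CD72 (3.09 ± 0.30), SPIB (2.01 ± 0.21) and MS4A1 (1.45 ± 0.26). Of the blood list PTPRC (1.74 ± 0.21), CD68 (2.61 ± 0.36), LYZ (2.20 ± 0.46) and CD3E (0.90 ± 0.18) all rose, as did CD3G (1.75) of the T lymphocyte list and ITGAM (2.52) of the monocyte list. EPCAM of the epithelial list fell (−1.29) and TP63 rose (0.96), while PDGFRB (0.50) and ACTA2 (0.71) of the fibroblast list did not pass. These contrasts were chosen after the planned additive fit had called 0 genes (3586 at an unadjusted p under 0.05, smallest adjusted p = 0.120). Without the control library 47 genes passed, 47 up and 0 down, and without a filter on low values 12, 12 up and 0 down, so no gene named here as fallen keeps its call in either. Without the MYC knockdown library 2345 genes passed and without the starved control library 2659.

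**Figure D3:**
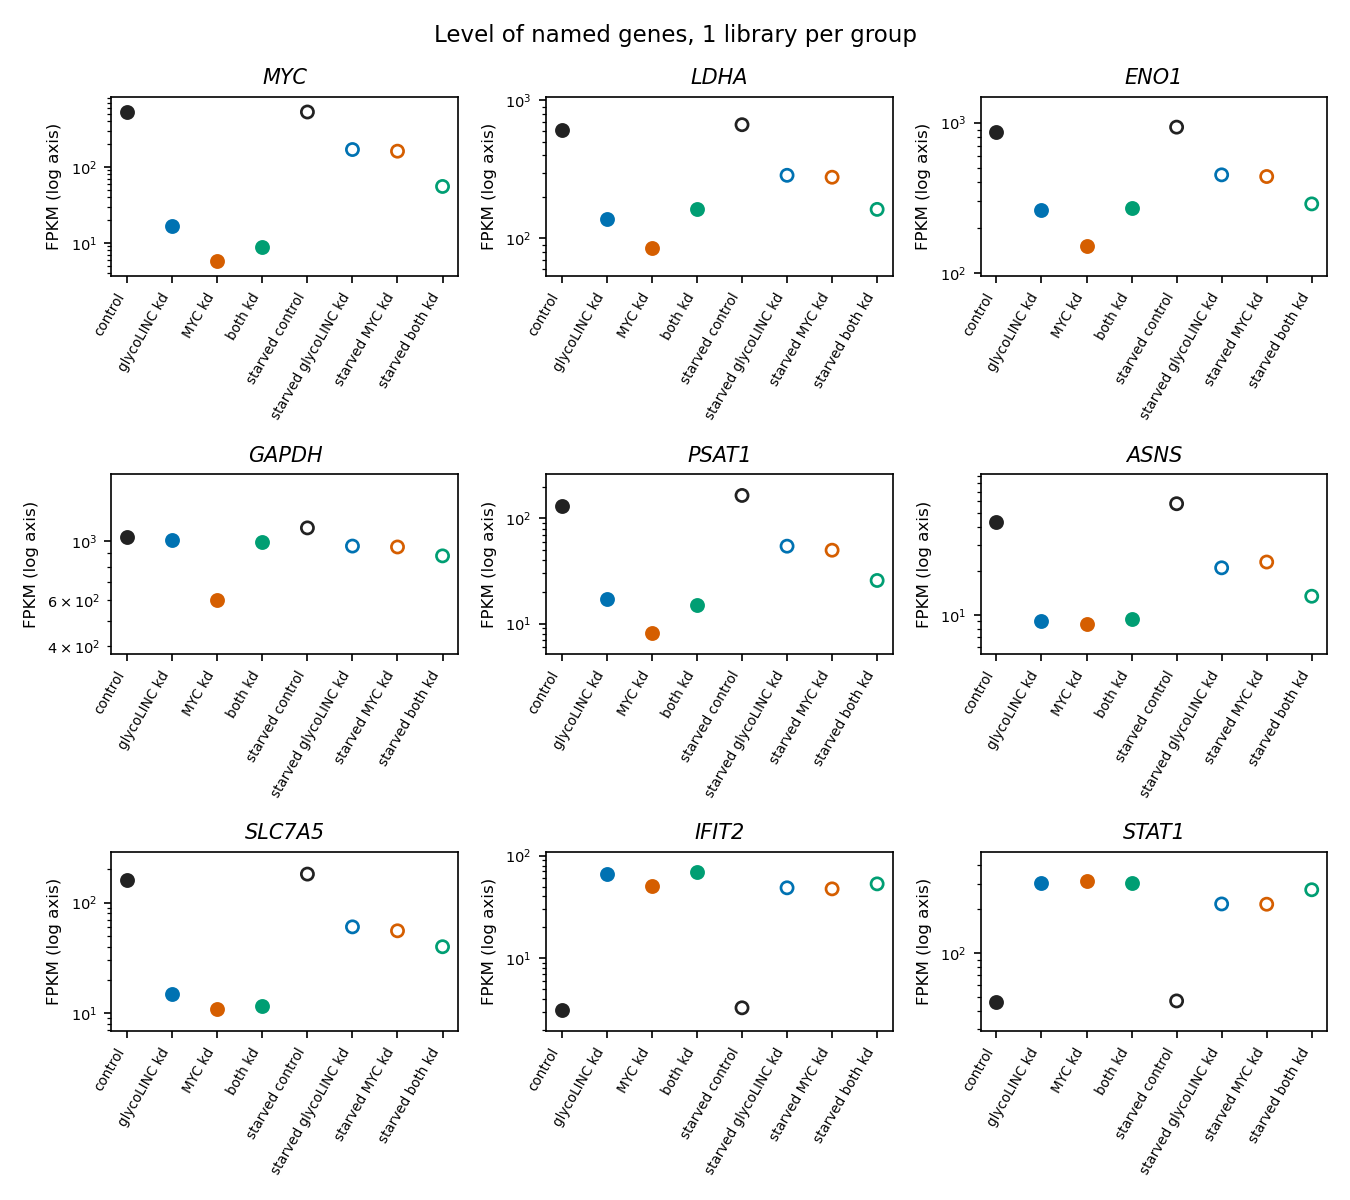
FPKM of named genes in each of the 8 libraries on log axes, each point 1 library. MYC is at 523 and 528 FPKM in the control and starved control libraries and between 5.77 and 169 FPKM in the libraries with a hairpin.

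In the libraries labelled MYC knockdown alone PHGDH fell by 2.08 ± 0.51 (adjusted p = 0.0193), PSAT1 by 2.77 ± 0.46 (adjusted p = 0.00789), PSPH by 1.44 ± 0.28, SHMT2 by 0.92 ± 0.23 and MTHFD2 by 1.47 ± 0.29. ASNS fell by 1.75 ± 0.25 (adjusted p = 0.00753), ATF4 by 1.43 ± 0.23 and TRIB3 by 0.77 ± 0.14, while DDIT3 (−0.10 ± 0.20, adjusted p = 0.721) did not pass. DDIT3 stood at 0.03 when each library was shifted to a median ratio of 0. LDHA fell by 2.05 ± 0.40 (adjusted p = 0.00995), ENO1 by a factor of 3.48 (adjusted p = 0.00987), PGK1 by 1.10 ± 0.19, PGAM1 by 0.99 ± 0.27 and PKM by 0.61 ± 0.17, while GAPDH (−0.52 ± 0.24, adjusted p = 0.126) did not pass. Of the 29 named genes that passed, 23 lost the call without the control library, 6 without the MYC knockdown library, 4 without the starved control library, and 3 each without the glycoLINC knockdown and starved glycoLINC knockdown libraries. MYC was at −2.27 (adjusted p = 0.0803) without the control library and at −2.67 (adjusted p = 0.0620) without the MYC knockdown library. In the planned additive fit these genes had values in the same direction, such as −1.69 ± 0.52 for PSAT1, −1.02 ± 0.33 for ASNS and −1.17 ± 0.43 for LDHA, and did not pass. The genes closest to the threshold there were NTMT1 (−1.39 ± 0.19), SETMAR (−1.26 ± 0.17), DNAAF5 (−1.26 ± 0.17) and PRXL2A (−1.03 ± 0.17) with lower values and ERO1B (0.86 ± 0.15), IGFL4 (0.80 ± 0.15), MT2A (1.45 ± 0.30) and CCR2 (1.49 ± 0.31) with higher ones.

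By list, 28 of 28 nucleolar MYC targets fell, with a median of −1.98, among them POLR1B of RNA polymerase I (−1.89), PES1 (−1.88) and ODC1 of polyamine synthesis (−1.57), and adjusted p = 0.589 with an estimated correlation. Of the interferon response genes, 24 of 25 rose (median 2.56), among them IFIT1 (3.26), IFIT3 (3.29) and STAT2 (2.56), and adjusted p = 0.589 with an estimated correlation. All 16 purine and pyrimidine synthesis genes fell (median −1.61), including GART (−1.50) and ATIC (−1.78), as did 18 of 20 tRNA synthetases (−1.23), including GARS1 (−1.73). So did 9 of 14 amino acid transporters (−1.37), including SLC7A5 (−2.72) and SLC1A5 (−2.07), and 8 of 9 lower glycolysis genes (−1.31), including the lactate transporter gene SLC16A1 (−2.33). Of the serine, glycine and one-carbon genes 12 of 16 fell and 1 rose, and of the amino acid response genes 13 of 19 fell and PPP1R15A rose (0.90). PPP1R15A was picked out after its value was seen. Fatty acid synthesis (9 of 10 fell, FASN −2.46), cholesterol synthesis (11 of 23 fell, DHCR7 −1.95) and S phase genes (15 of 26 fell, MCM4 −1.52) were also lower. For the purine and pyrimidine, tRNA synthetase, transporter, lower glycolysis, serine, amino acid response, fatty acid, cholesterol and S phase lists, camera placed the list lower with the preset correlation, and adjusted p = 0.589 with an estimated correlation. Ribosomal proteins were placed lower (5 of 83 fell, RPL22L1 −1.97), with adjusted p = 0.668 with an estimated correlation. Adjusted over the list alone, 18 S phase genes fell, 14 cholesterol genes fell and 1 rose, 13 serine and one-carbon genes fell, 10 fatty acid genes fell and 3 ribosomal protein genes fell. The other lists in this paragraph kept their counts.

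The other lists were not called by camera in the libraries labelled MYC knockdown alone. Of the heat shock genes 4 of 9 fell, among them the mitochondrial chaperonin gene HSPE1 (−2.52). Of 14 upper glycolysis genes 7 fell, including HK2 (−1.95), and 2 rose, including the glucose transporter gene SLC2A3 (2.45). Of 10 hypoxia genes 4 fell, with VEGFA at −2.09, and 2 rose (3 rose and 5 fell adjusted over the list alone). Of 12 NRF2 and pentose phosphate genes 7 fell and 2 rose. Of 17 p53 targets 4 rose, with BTG2 at 1.70, and AEN fell (−1.34), and of 6 immediate early genes 3 rose, with IER2 at 1.20. Of 17 autophagy and lysosome genes 5 rose, with CTSB at 1.15, and CTSD fell by 0.61 (4 rose and 1 fell adjusted over the list alone). Of 16 endoplasmic reticulum chaperone genes 3 fell, with XBP1 at −1.29, of 24 G2/M genes MKI67 rose (0.89), and of 62 replication histones H2AC25 fell (−0.82; 0 adjusted over the list alone). For the histone list the median was −0.04 and the test pointed higher. In the planned additive fit no list member passed over all genes. Adjusted over the list alone, 25 interferon genes rose and 27 nucleolar targets, 17 tRNA synthetases, 16 purine and pyrimidine genes, 9 amino acid response genes, 9 fatty acid genes, 6 transporters and 4 heat shock genes fell, and of the NRF2 list 4 fell and NQO1 rose (0.63). camera placed 12 lists there, 1 higher and 11 lower, with adjusted p = 0.569 with an estimated correlation for ribosomal proteins and S phase and adjusted p = 0.556 with an estimated correlation for the other 10. The G2/M list had a median of −0.06 and a test pointing higher.

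**Figure D4:**
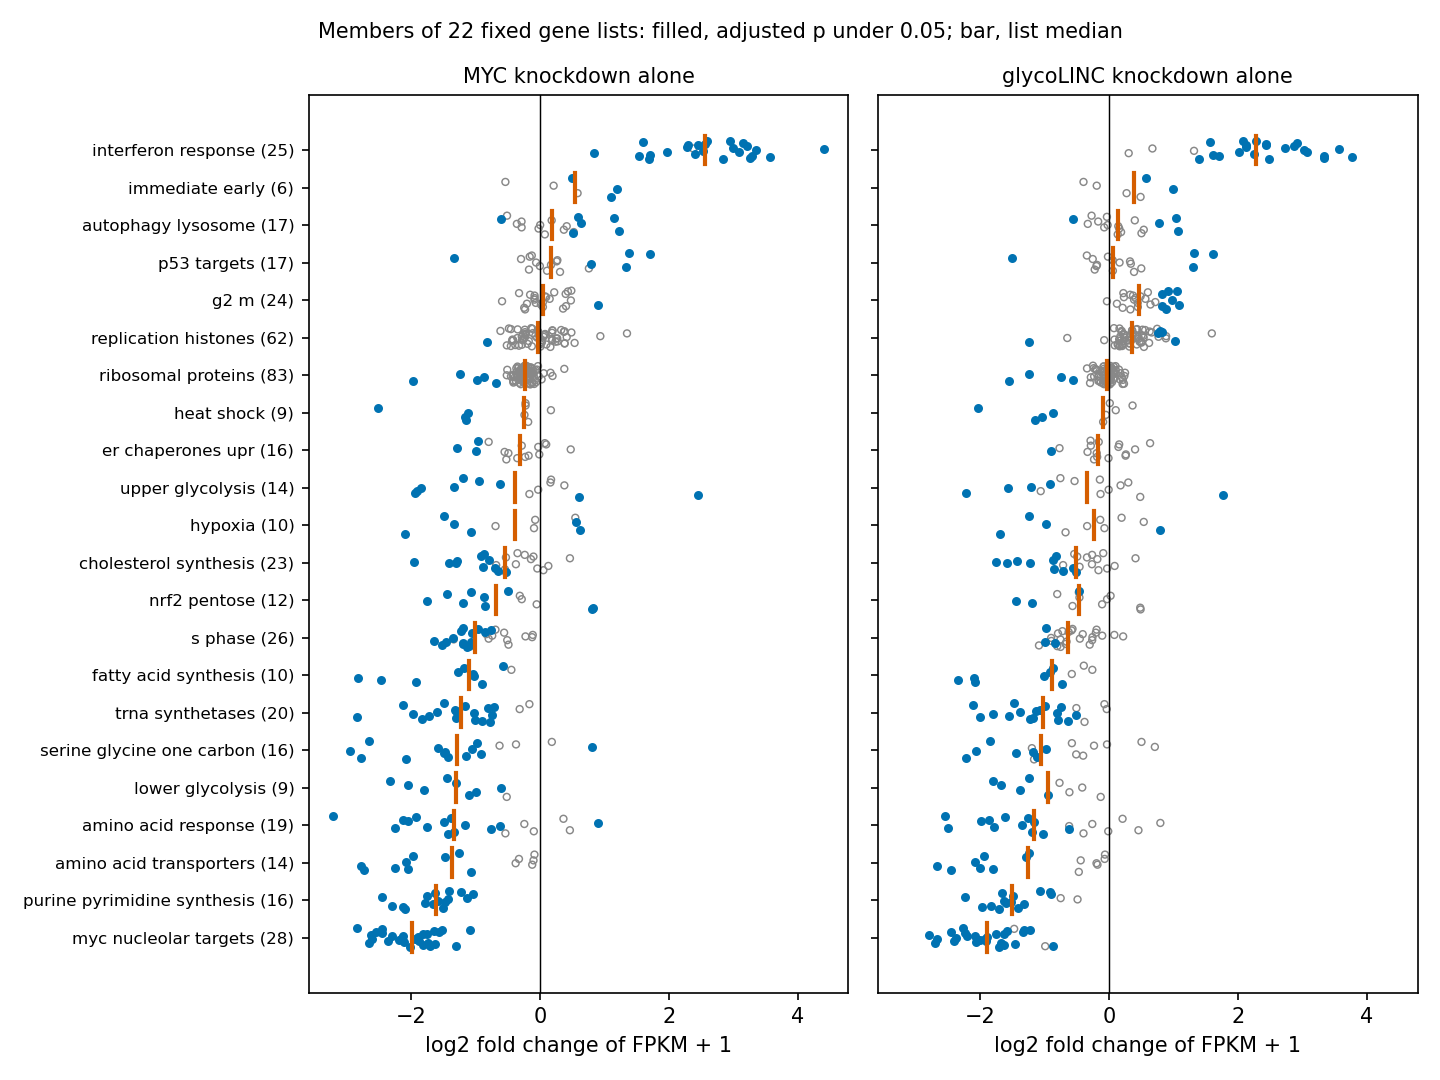
Log2 fold change of FPKM + 1 for the members of 22 gene lists, with MYC knockdown alone and glycoLINC knockdown alone in separate panels, each point 1 gene (filled for adjusted p under 0.05) and a bar at the list median. The nucleolar MYC targets have medians of −1.98 (MYC knockdown alone) and −1.90 (glycoLINC knockdown alone), and the interferon list 2.56 and 2.27.

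The comparison of libraries with and without the glycoLINC hairpin asks what this noncoding RNA controls. In the libraries labelled glycoLINC knockdown alone 26 of 28 nucleolar MYC targets fell and 22 of 25 interferon response genes rose, and for both lists adjusted p = 0.577 with an estimated correlation. MYC fell by 3.27 ± 0.90 (SE, log2, adjusted p = 0.0354), FKBP4 by 3.08 ± 0.69 (adjusted p = 0.0209), the deubiquitinase gene USP36 by 2.82 ± 0.42 (adjusted p = 0.0111) and MYBBP1A, a nucleolar gene, by 2.79 ± 0.55 (adjusted p = 0.0152). FJX1 (−2.89 ± 0.63) and PODXL2 (−2.73 ± 0.60) fell too, and so did HPDL (−3.24 ± 0.86, adjusted p = 0.0323) and GALNT18 (−2.95 ± 0.74, adjusted p = 0.0273), which with a pseudocount of 0.1 had adjusted p = 0.0516 and 0.0548. IFIT2 rose by 3.77 ± 0.17 (adjusted p = 0.000515), RSAD2 by 3.63 ± 0.29, SLFN5 by 3.71 ± 0.19, IFIT3 by 3.33 ± 0.17, CMPK2 by 3.35 ± 0.18, IFI6 by 3.57 ± 0.50, ZBP1 by 3.38 ± 0.34 and CCL3 by 3.76 ± 0.40. In all, 3004 genes passed limma's test, 1367 up and 1637 down, but 12 up and 0 down without a filter on low values. B lymphocyte genes moved with these groups, with 9 of 13 that rose. So did PTPRC (1.61 ± 0.21), CD68 (1.96 ± 0.36), LYZ (1.74 ± 0.46) and CD3E (0.85 ± 0.18), CD3G (1.31) and TP63 (0.83), while ITGAM (1.70) and EPCAM (−1.04) did not pass. Without the control library 35 genes passed (34 up and 1 down), without the glycoLINC knockdown library 6 (6 up and 0 down), without the starved glycoLINC knockdown library 43 (38 up and 5 down) and without the starved control library 1689.

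Of the metabolic genes, PSAT1 fell by 2.22 ± 0.46 (adjusted p = 0.0168), PSPH by 1.12 ± 0.28, MTHFD2 by 1.18 ± 0.29, ASNS by 1.78 ± 0.25, ATF4 by 1.02 ± 0.23, TRIB3 by 0.62 ± 0.14, LDHA by 1.68 ± 0.40, ENO1 by 1.39 ± 0.35 and PGK1 by 0.96 ± 0.19 in the libraries labelled glycoLINC knockdown alone. PHGDH (−1.17 ± 0.51, adjusted p = 0.127), SHMT2 (−0.51 ± 0.23, adjusted p = 0.136), DDIT3 (−0.01 ± 0.20, adjusted p = 0.965) and the glycolytic genes GAPDH (−0.13 ± 0.24, adjusted p = 0.707), PGAM1 (−0.62 ± 0.27, adjusted p = 0.125) and PKM (−0.42 ± 0.17, adjusted p = 0.108) did not pass. Of the 25 named genes that passed, 21 lost the call without the glycoLINC knockdown library, 19 without the control library, 19 without the starved glycoLINC knockdown library, 3 without the starved control library and 1 each without the double knockdown and starved double knockdown libraries. MYC was the gene lost in those last cases (adjusted p = 0.0568 and 0.0564), and stood at −1.55 (adjusted p = 0.198) without the control library, −2.82 (adjusted p = 0.233) without the glycoLINC knockdown library and −3.73 (adjusted p = 0.114) without its starved counterpart. The planned additive fit called 0 genes (1933 at an unadjusted p under 0.05, smallest adjusted p = 0.264) but 2191, 730 up and 1461 down, without the MYC knockdown library. MYC was then at −2.73 (adjusted p = 0.0391). With all 8 libraries MYC stood at −1.89 ± 0.82. The genes closest to the threshold were CEP70 (0.82 ± 0.12), IFT25 (0.87 ± 0.14), TAX1BP3 (1.34 ± 0.23) and IFT80 (0.68 ± 0.13) with higher values. CEP70, IFT25 and IFT80 are genes of the centrosome and cilium. Those with lower values were DNAAF5 (−1.17 ± 0.17), QPCTL (−0.76 ± 0.13), SETMAR (−0.99 ± 0.17) and PM20D2 (−0.97 ± 0.17).

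By list, under the glycoLINC label alone, 26 of 28 nucleolar MYC targets fell (median −1.90), among them GNL3 (−2.08) and PES1 (−1.91), and 22 of 25 interferon genes rose (median 2.27). Of the purine and pyrimidine genes 14 of 16 fell, including IMPDH1 (−1.63), and 16 of 20 tRNA synthetases fell, including YARS1 (−1.48). Of the transporters 8 of 14 fell, including SLC1A5 (−2.08), of the amino acid response genes 12 of 19, including GPT2 (−1.26), of the fatty acid genes 7 of 10, including ACACA (−2.08), and of the cholesterol genes 10 of 23, including CYP51A1 (−1.58). For each of these 8 lists adjusted p = 0.577 with an estimated correlation. Of the lower glycolysis genes 5 of 9 fell (PGK1, ENO1, LDHA, SLC16A1 and SLC16A3, median of the list −0.96) and of the serine, glycine and one-carbon genes 7 of 16, including MTHFD1 (−1.45). Of the G2/M genes 7 of 24 rose, including MKI67 (1.09), ASPM (0.91) and HMMR (1.05), and of the replication histones 4 of 62 rose, including H3C6 (0.76), and H2AC25 fell (−1.25). For these 4 lists of lower glycolysis, serine, G2/M and histone genes adjusted p = 0.587 with an estimated correlation. Of the S phase genes MCM7 (−0.85), MCM10 (−0.99) and SLBP (−0.97) fell, with adjusted p = 0.599 with an estimated correlation. Adjusted over the list alone, 27 nucleolar targets, 17 tRNA synthetases, 15 purine and pyrimidine genes, 13 amino acid response genes (1 rose), 11 cholesterol genes, 8 serine and one-carbon genes (1 rose) and 0 S phase genes fell, 1 histone fell and 0 rose, and the other counts in this paragraph held.

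The remaining lists were not called by camera under the glycoLINC label alone. HK2 (−2.22), PFKM, PFKP and PFKFB3 of upper glycolysis fell and SLC2A3 rose (1.76). VEGFA (−1.69), PDK1 and ERO1A of the hypoxia list fell and BNIP3L rose (0.79). HSPA8 (−1.16), HSPE1, HSPH1 and HSP90AA1 of the heat shock list fell. TXNRD1 (−1.19), SRXN1 and GSR of the NRF2 list fell. BTG2 (1.60), TP53INP1 and TP53I3 of the p53 list rose and AEN fell (−1.51). CTSB (1.03), NBR1 and WIPI1 of the lysosome list rose and CTSD fell (−0.56). IER2 (0.99) and KLF6 rose, SDF2L1 of the endoplasmic reticulum fell (−0.90), and RPL22L1 (−1.56), RPL7L1, RPL37 and RPL26L1 fell among 83 ribosomal protein genes. Adjusted over the list alone, the hypoxia list had 2 that rose and 4 that fell, upper glycolysis 2 and 4, NRF2 2 that fell and ribosomal proteins 1; the rest kept their counts. In the planned additive fit camera placed 11 lists, 3 higher and 8 lower, with adjusted p = 0.669 with an estimated correlation for lower glycolysis and adjusted p = 0.583 with an estimated correlation for the other 10; adjusted over the list alone 17 nucleolar targets fell, and over all genes 0.

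Whether the responses add up was asked with interaction terms. The interferon-induced gene IFIT2 rose by less with both hairpins than the sum of its changes with either: it was at 3.12 FPKM in the control library, 65.8 FPKM with the glycoLINC hairpin, 51.0 FPKM with the MYC hairpin and 68.4 FPKM with both. The glycoLINC by MYC term passed limma's test for 29 genes, all negative, with 2735 at an unadjusted p under 0.05. It was led by IFIT2 (−3.48 ± 0.24), SLFN5 (−3.57 ± 0.26) and IFIT1 (−3.06 ± 0.24), each with adjusted p = 0.00855. Of the 29, 9 were on the interferon list, and the rest included SAMD9L, CMPK2 and RSAD2. Independent draws of genes would give 0.0700, but genes that move together are not independent draws. The 2735 genes leave open a departure from additivity that is not particular to interferon genes. Against the libraries without hairpins, those labelled double knockdown had 4294 genes past the threshold, 1717 up and 2577 down (2088 up and 2018 down after quantile normalisation, and 1145 up and 1496 down without a filter on low values), around a median of −0.09. Of the nucleolar targets 28 of 28 fell and of the interferon genes 24 of 25 rose, the same counts adjusted over the list alone, and adjusted p = 0.607 with an estimated correlation for both. B lymphocyte genes moved with these groups, with 12 of 13 that rose, and none of 7 tested genes of adherent epithelial cells passed. In the starved double knockdown library, however, 13 of 16 epithelial genes were at 1 FPKM or more, against 4 in the control and 8 in the starved control library. A glycoLINC hairpin on top of a MYC hairpin passed for 0 genes in limma (200 at an unadjusted p under 0.05). A MYC hairpin on top of a glycoLINC hairpin also passed for 0 genes (250 at an unadjusted p under 0.05). Both contrasts average the 2 media, so opposite changes cancel. For glycoLINC on top of MYC, 234 genes were at least 2-fold apart in control medium and 107 in starved medium. The S phase list had a median log2 difference of 0.74 in control medium (26 of 26 higher) and −0.37 in starved medium (0 of 26 higher). The cholesterol synthesis list was lower in both (−0.11 and −0.19). The interactions of starvation with the MYC hairpin and with the glycoLINC hairpin each called 0 genes (70 and 123 at an unadjusted p under 0.05). The 29 genes became 0 without a filter on low values and 0 without the control, glycoLINC knockdown, double knockdown, starved glycoLINC knockdown or starved double knockdown library, 13 (1 positive) without the starved control and 44 (2 positive) without the MYC knockdown library. Without the starved MYC knockdown library they became 3053, of which 1913 were positive and 1140 negative. For both hairpins 774, 2782 and 513 genes passed without the control, starved control and starved double knockdown libraries.

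The responses to the 2 hairpins were compared across genes, which are not independent replicates. The additive coefficients of the MYC and glycoLINC hairpins correlated at r = 0.838 over 10363 genes, against a mean of 0.00172 and a largest absolute value of 0.0634 simulated without effects, with a covariance of 0.170 against 6.3e-05. The simulation drew each gene independently. Its values therefore do not show how large r can be by chance when genes move together. In control medium alone r was 0.605, and in starved medium alone 0.852. For each knockdown alone, which share control libraries, r was 0.947 against 0.502 simulated, with a covariance of 0.569 against 0.0372. Of the genes that rose under each knockdown alone, 1143 were shared, among them IFIT2, RSAD2 and SLFN5, against 212 for independent lists. Of those that fell, 1568 were shared, among them MYC, PSAT1 and FKBP4, against 420. In opposite directions 0 genes changed. Simulations without effects shared 0, but they hold no changed genes, so this is no reference for lists of this length. The controls could not be divided into parts of at least 2 libraries, so part of the excess may come from sharing them.

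The table of Ensembl transcripts covers coding and noncoding RNA under identifiers alone. The additive limma fit called 0 of 87405 transcripts for starvation (5972 at an unadjusted p under 0.05), 0 for the MYC hairpin (33645) and 0 for the glycoLINC hairpin (14219), with smallest adjusted p of 0.689, 0.0588 and 0.267. Without single libraries these counts changed: 522 for starvation without the control library, 7080 and 27333 for the MYC hairpin without the MYC knockdown and double knockdown libraries, and 20172 and 4009 for the glycoLINC hairpin without the same libraries. The median for starvation over all transcripts was 0.14. With the glycoLINC by MYC term 1589 transcripts passed in starved medium, all higher, but 0 after a shift of each library to a median ratio of 0 (8528 at an unadjusted p under 0.05). Under the MYC label alone 8489 transcripts rose and 27347 fell around a median of −0.32 over all transcripts, and after a shift of each library to a median ratio of 0 the division was 16691 and 17728. Under the glycoLINC label alone 7959 rose and 15204 fell around −0.12 (11572 and 13360 after the shift), and with both hairpins 8554 rose and 26361 fell around −0.29 (17185 and 17809). ENST00000382040.3 rose by 4.30 ± 0.27 and ENST00000339145.4 by 4.23 ± 0.41 under the MYC label alone, and ENST00000377970.2 fell by 4.32 ± 0.66 and ENST00000524013.1 by 4.32 ± 0.66. The transcripts that fell had nearly the same FPKM in each library, such as 166 and 174 in control and 1.55 and 1.63 in MYC knockdown. They may share reads and are not separate results. Without single libraries the total under the MYC label alone was 15709 (control), 20639 (MYC knockdown) and 23701 (starved control), under the glycoLINC label alone 4631 (control), 0 (glycoLINC knockdown) and 3944 (starved glycoLINC knockdown), and with both 16100 (control) and 22522 (starved double knockdown).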

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

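The interaction test was planned; the tests of shared control libraries, of the level of MYC, of a response to hairpins as such and of splits of the libraries were chosen after the result was seen.

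The glycoLINC by MYC term passed for 29 genes, so in the fit of all 8 libraries the effect of the glycoLINC hairpin on these genes differed between libraries with and without the MYC hairpin. The calls do not hold without some single libraries, the control among them, or without a filter on low values. The clearest were the interferon-induced genes IFIT2 (−3.48), SLFN5 (−3.57) and IFIT1 (−3.06), negative because each rose with either hairpin and by less than the sum of these changes with both.

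The responses to the 2 knockdowns coincided across genes. Noise of a single shared control library is argued against as the whole cause, since pairs of libraries that share none still correlated at 0.854 or more. These pairs use the control library in one and the starved control library in the other, which differed at least 2-fold in 22 genes. A trait common to both libraries without a hairpin is therefore not tested and stays open. A lower MYC level under either label may account for it, as MYC fell under the glycoLINC label alone with a log2 fold change of −3.27, though this call is lost without any of 5 single libraries. A response to hairpins as such cannot be told apart from this, because 0 libraries with a hairpin kept MYC at 50% or more of the lower control. A direct action of glycoLINC on MYC and an exchange of labels or columns stay open and untested, as glycoLINC itself was not analysed here. The libraries labelled glycoLINC knockdown and double knockdown differed at least 2-fold in 23 genes, and those labelled starved glycoLINC knockdown and starved MYC knockdown in 15 genes.

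Each planned factor called 0 genes or transcripts, and no split can call fewer, so the 33 splits of the 8 libraries into 4 and 4 compared (those that follow another factor were left out) are all as large by construction and say nothing about chance for the 6 planned counts. At an unadjusted p under 0.05, 12 of the 33 splits had as many genes as starvation (243), 2 as many as the MYC hairpin (3586) and 3 as many as the glycoLINC hairpin (1933), the real split included. The highest count of calls in another split was 11 genes for starvation, 0 for the MYC hairpin and 2016 for the glycoLINC hairpin in the mRNA table, and 6933, 16960 and 17205 in the Ensembl table. The splits with 2016 and more calls listed here point to a structure of the samples: all keep together the control and starved control libraries, which are the libraries without a hairpin.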

How the results depend on the processing

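Among the alternatives given here, the added term in the starvation fit, those for each knockdown alone, for both and for a knockdown on top of the other, and the correlation for each knockdown alone were chosen after the data were seen; the rest were planned. Of 112 values of the comparisons under other settings 97 kept their direction and their side of the threshold (counts within 1.5 times), 11 were weaker, 2 stronger and 2 moved, and 0 reversed. With single libraries left out 159 of 192 were kept. A count of 0 that stayed 0 was taken as kept, although it had no call or direction to lose. These shares therefore overstate how stable the calls are. The 29 interaction genes became 0 without a filter, 44 with a filter at a mean FPKM of 5 and 10 in a robust fit without trend. Without a filter 12 genes passed under each knockdown alone, 12 up and 0 down, and 2641 under both, with 16847 genes tested in place of 10363. More tests alone can raise an adjusted p by at most the ratio of these numbers. The smallest limma adjusted p went from 0.000459 to 0.0417 under the MYC label alone and from 0.000515 to 0.0402 under the glycoLINC label alone. The number tested is thus argued against as the whole cause for these 2 contrasts. The term of glycoLINC by MYC raised the transcripts called for starvation from 0 to 1589, all higher, and to 0 after a shift of each library to a median ratio of 0. With an estimated correlation 0 gene lists were called in each of the 6 contrasts. The correlation of the knockdown responses was 0.605 in control medium alone and 0.947 for each knockdown alone. The cause of these moves was otherwise not tested. Leaving out single libraries gave 0 to 2191 genes for the glycoLINC hairpin, 0 to 3053 for the interaction, 47 to 5363 under the MYC label alone, 6 to 4453 under the glycoLINC label alone, 513 to 5448 with both and 0 to 1 for glycoLINC on top of MYC; for Ensembl transcripts it gave 0 to 522 (starvation), 0 to 27333 (MYC hairpin), 0 to 20172 (glycoLINC hairpin), 15709 to 41593 (MYC alone), 0 to 31691 (glycoLINC alone) and 16100 to 41738 (both). The sum of Ensembl transcripts per gene, a planned choice, was not run, and each transcript was tested singly. No paired analysis was possible because each group has 1 library and the groups share a single replicate number; libraries that differ in 1 factor are matched through the additive fit instead. Unknown depth limits low genes, for which the spread cannot be divided into counting error and the rest.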

Other observations

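The tests of 8 further B lymphocyte genes and of mixing were set out before their results were seen; the tests of name matching and of mixing with HepG2 cells, the other ends of the mixture, the spread of the gaps and the epithelial values, were chosen after.

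B lineage genes beyond the usual markers were also at high levels. In the control library SPIB, a transcription factor of B cells, was at 33.5 FPKM and rose to 172 FPKM under the MYC label, and CD79B of the B cell receptor went from 117 to 547 FPKM under the same label. CD72, a coreceptor, went from 7.26 FPKM to 56.8 FPKM under the glycoLINC label. FCER2 (CD23), a receptor of activated B cells, was at 64.1 FPKM in the control library and 190 FPKM under the MYC label. The median over 14 B lymphocyte genes was 41.7 FPKM in the control library, 43.1 FPKM in the starved control and 122 FPKM under the MYC label.

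Some of 16 genes of adherent epithelial cells, a list written after the data were seen, were higher in 2 libraries, while KRT8, KRT18 and TEAD1 of the list were above 1 FPKM in all 8. In the starved double knockdown library KRT7 was at 15.1 FPKM, S100A6 at 15.3 FPKM, YAP1 at 6.13 FPKM, KRT17 at 3.60 FPKM and EGFR at 2.82 FPKM, and 13 of 16 genes were at 1 FPKM or more. In the starved control library KRT7 was at 1.54 FPKM, S100A6 at 4.49 FPKM and KRT17 at 4.25 FPKM, and 8 of 16 genes reached 1 FPKM, against 3 or 4 in the others. The hepatocyte enzyme gene CPS1 was at 3.08 FPKM in the starved double knockdown library and at most 0.827 FPKM in the others.

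Hepatocyte genes were near 0 and B lymphocyte genes high in all 8 libraries. A failure to match names is argued against, as 100% of the hepatocyte list had a named transcript. B cells mixed into HepG2 cultures are argued against too, since the median over that list of the highest FPKM in any library was 0.113. The hypothesis that all 8 libraries may come from B lymphoid cells passed its test, with 7 of 8 further B lymphocyte genes at a mean of at least 1 FPKM. Other B lymphocyte genes had already been seen at high levels, so a pass was likely and adds little. The test cannot tell B lymphoid cells alone from a mixture with cells other than hepatocytes. How B lymphoid cells could have come under the label HepG2 was not tested, and no biological explanation was tested.

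The starved libraries labelled glycoLINC knockdown and MYC knockdown lay between the starved control and the unstarved glycoLINC knockdown library. For genes 2 to 4 fold apart, a linear mixture of these ends predicts the same fraction from genes higher and lower in the control (a gap of at most 0.1 was set as the bound), and the gaps were 0.0556 and 0.0592, with 0.0177 and 0.0171 for the double knockdown library as the other end and 0.102 and 0.132 for the MYC knockdown library. A graded change of every gene by the same share of its log2 fold gave gaps of 0.155 ± 0.00732 (SE over resampled genes) and 0.140 ± 0.00725, with 0.199 and 0.183 for the double knockdown end and 0.139 ± 0.00829 and 0.114 ± 0.00786 for the MYC knockdown end. For genes over 4 fold apart the linear gaps were 0.0108 and 0.00701 with the glycoLINC knockdown end, 0.0307 and 0.0216 with the double knockdown end and 0.270 and 0.255 with the MYC knockdown end, and the graded gaps 0.331 and 0.334, 0.338 and 0.333, and 0.169 and 0.180. For the glycoLINC knockdown end, set in advance, a graded change of every gene by an equal share is argued against for both libraries. The SE treats genes as independent, which they are not. A graded change with shares that differ between genes was not tested and stays open. A mixture of RNA or cells, incomplete knockdown in part of the cells and an effect of the medium stay open too. The 2 starved libraries differed from each other at least 2-fold in 15 genes, so they are not separate checks.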
